A study of Mus musculus with 6 samples.

How the data were processed

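Gene expression was measured by RNA sequencing in 6 libraries of skin Tregs, 3 per group. Per the labels' protocols, sorted cells were frozen in lysis buffer, total RNA was purified with a micro-scale column kit, cDNA was made with SMART-seq v4, a template-switching method for small amounts of RNA that does not mark strand, and libraries were made with Nextera XT. The reads were aligned to mm10 with STAR, per the submitters' processing notes. The read counter, the annotation, the versions and the strand setting are not given in the sources used here. The deposited values are RPKM, calculated by the authors with the gene length given in the same table, 1 column per library and rounded to 3 decimals. A test on the table showed that each of the 10816 listed genes has at least 3 RPM (reads scaled to library size only) in every library of at least 1 group, so genes under that level in both groups are outside the comparison. The table holds no zeros, and 0 columns of per-sample values were left unused.

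Depth was recovered from the RPKM values. Multiplied by gene length, the values of low genes are whole multiples of what 1 read is worth, and in each library 100% of the values that rounding allowed to be checked were whole within 0.1 read. This gave 18423290, 23027887 and 16316797 reads for BSA replicates 1 to 3 and 14348963, 16972187 and 17738631 for PA replicates 1 to 3, of which the listed genes hold 98.9% to 99.3%. The level of 3 RPM corresponds to 43.0 to 69.1 reads in a library. The 10 genes with most reads took 2.59% to 2.85% of each library, and B2m had the highest RPKM in all 6. Replicate libraries of a group differed by 8.45 to 13.7 times the chi-square expected from sampling alone, and libraries of different groups by 21.4 to 40.0 times, so no library was a copy of another.

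Groups and replicate numbers were taken from the sample titles. Genes with an RPKM of at least 1 in at least 3 of the 6 libraries, whatever their group, were kept (9763 genes). PA was compared with BSA on log2(RPKM + 1) with limma 3.58.1 in R 4.3.3, with empirical Bayes moderation that follows the trend of variance with expression, group as the only term and 4 residual degrees of freedom. Tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method over all genes tested, with 0.05 as the threshold. Rank or permutation tests of 3 against 3 cannot give a p below 0.1. Standard errors are those of the moderated fit, and values in RPKM are given as mean ± SD over 3 libraries. A count test was not used, because the deposited unit is RPKM.

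Before the data were examined, 22 lists of genes (programs of Tregs, lipid metabolism, stress, division and signaling) and 8 lists of markers of other skin cells were written from textbook knowledge. Each was tested with camera (two-sided, preset inter-gene correlation of 0.01), adjusted over the 22 lists or over the marker lists as their own family, and again with an estimated correlation. Members were counted from the fit over all genes and also with p-values adjusted over the list alone. The rule for named genes was set at the same time. It takes the 12 largest rises and the 12 largest falls among genes past the threshold whose groups do not overlap and whose mean in the higher group is at least 5 RPKM, leaving out predicted genes, up to 4 members of each program list with the smallest p, and 24 anchor genes. Of these, 108 genes had values, and 51 were higher, 46 lower and 11 did not pass. Some of these genes are not reported here. Other list members are named as examples and were chosen after their values were seen.

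The alternatives were other pseudocounts (0.1 and 0.5), no filter and a filter at 5 RPKM, 3 scalings between libraries (rescaling to a common sum, quantile normalization and median centring), no variance trend, array quality weights, the replicate number as a block, leaving out each library, a threshold of 0.1, camera with an estimated correlation, and fry. A weighted fit (voom) on the recovered reads and a correction for GC content and gene length were added after seeing the data, before either had been run.

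The test was checked on simulated reads with the means and depths of these libraries, dispersion averaged over genes of like expression, and 200 genes changed by known folds. Each gene was drawn independently, so the correlation between genes in these libraries was not simulated. Far fewer genes were changed than were called in the real comparison, so the shares of recovered and false calls hold for that setting only. In 9760 genes tested for simulated PA against BSA, 66% of 50 genes changed 1.5-fold and 98% of 50 genes changed 2-fold were called. Over 10 such simulations 5.93% of 1484 calls were false, and 10 simulations without any change gave 1 call in all. Entrez gene identifiers matched RefSeq genes of GRCm38.p6, the assembly behind mm10, for 10810 genes (99.9%), from which coordinates were taken, 1-based. GC content (97.9% of genes) and overlaps of exons between genes were taken from GENCODE M21 on the same assembly. Figures were drawn with matplotlib 3.10.9.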

Results

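The data set holds 6 RNA sequencing libraries of regulatory T cells (Tregs) from mouse skin, 3 from cells cultured with palmitic acid (PA) and 3 from cells cultured with its carrier, bovine serum albumin (BSA). Tregs are the CD4 T cells that restrain immune responses and depend on the transcription factor Foxp3. They were sorted from the skin of mice 2 to 3 weeks old that carried knock-in reporters at Pparg (tdTomato) and Foxp3 (Thy1.1) and had received 2 injections of IL-33 at 100 ng per g of body weight. Culture lasted 3 days in medium holding IL-33 (20 ng/ml) and IL-2 (2000 U/ml), with PA at 300 µM on BSA or with BSA alone, and live Tregs were sorted again before the RNA was taken. Palmitic acid is the most common saturated fatty acid of the body. The libraries held 16316797 to 23027887 counted reads in the BSA group and 14348963 to 17738631 in the PA group, as recovered from the spacing of the RPKM values (reads scaled to gene length and library size). The table lists 10816 genes, and 9763 of them reached an RPKM of 1 in at least 3 libraries and were tested.

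The comparison asks how palmitic acid changes the transcripts of skin Tregs. In PA, single genes of fatty acid handling (Cpt1a, Dgat2 and Plin2) rose, while most genes tested for making cholesterol and for dividing fell, and so did those of the fatty acid desaturases. Cpt1a, which encodes the enzyme that loads long-chain fatty acids onto carnitine for entry into mitochondria, went from 20.4 ± 1.13 to 46.7 ± 1.94 RPKM (mean ± SD, n = 3 in each group). Hmgcs1, an early enzyme of cholesterol synthesis, went from 36.5 ± 1.41 to 19.1 ± 1.63 RPKM (n = 3). Foxp3 itself rose by a factor of 1.30, from 12.1 ± 0.852 to 15.7 ± 0.101 RPKM (n = 3), while Tbx21, which encodes the type 1 T helper factor T-bet, went from 8.17 ± 3.54 to 1.53 ± 0.653 RPKM (n = 3).

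At a limma adjusted p below 0.05, 870 genes were higher and 915 lower in PA, together 18.3% of the genes tested. Most of these changes were small: the median absolute log2 fold change of the called genes was 0.40 on the log2(RPKM + 1) scale, 26 genes rose by at least 1 and 9 fell by at least 1. The first principal component held 57.2% of the variance and separated both groups, and the second held 13.2%. On the second, BSA replicate 3 (-8.09) and PA replicate 3 (-8.41) lay apart from the other 4 libraries (1.92 to 5.83). In 3505 of the tested genes (35.9%) the 3 PA values all lay on one side of the 3 BSA values, against 10% by chance. Without BSA replicate 2 the number of genes higher in PA was 555. The labels do not say that the replicates came from separate mice or cultures, so the p-values measure only the spread between these samples.

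**Figure D1:**
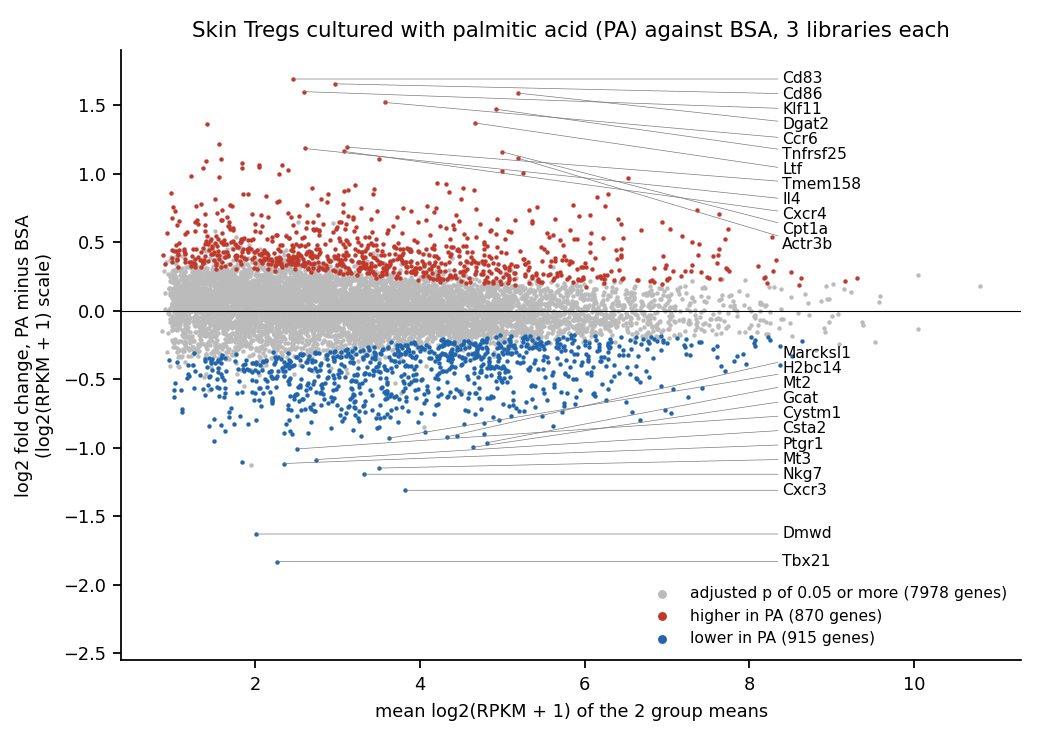
Log2 fold change of each tested gene (PA minus BSA, on the log2(RPKM + 1) scale) against the mean log2(RPKM + 1) of both group means, one point per gene. Red points are the 870 genes higher and blue points the 915 genes lower in PA, and the 12 largest rises and 12 largest falls chosen by the rule for named genes carry their symbols.

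Among genes with a mean of at least 5 RPKM in the higher group and no overlap between the groups, the largest rises included surface proteins of immune cells. Cd83 went from 2.09 ± 0.523 to 8.88 ± 0.504 RPKM (log2 fold change 1.69 ± 0.12 SE, adjusted p = 1.10e-05), and Cd86, a costimulatory ligand of CD28 and CTLA-4, from 3.43 ± 0.592 to 13.0 ± 1.92 RPKM (1.65 ± 0.12, adjusted p = 1.10e-05). Dendritic cells carry both proteins, and the antigen presentation genes Cd74 (log2 fold change -0.16) and H2-Ab1 (-0.24) did not pass the test. Tnfrsf25, the TNF receptor family member DR3, was the gene with the smallest p in this comparison and rose by a factor of 2.87, from 17.3 ± 0.712 to 49.7 ± 0.973 RPKM (1.47 ± 0.06, adjusted p = 1.40e-07). Ccr6 rose by 1.52, Il4 by 1.18 and Cxcr4, the receptor of the chemokine CXCL12, by 1.16 on the log2 scale. The transcription factor gene Klf11 rose by a factor of 3.86, and on the log2 scale the triglyceride synthesis gene Dgat2 rose by 1.59, the lactoferrin gene Ltf by 1.37, Tmem158 by 1.19, Cpt1a by 1.16 and Actr3b by 1.11.

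The largest falls were those of Tbx21 (-1.83 ± 0.24 SE, adjusted p = 0.000294) and Dmwd (-1.63 ± 0.14, adjusted p = 3.29e-05), followed by the chemokine receptor gene Cxcr3 (-1.31) and the cytotoxic granule gene Nkg7 (-1.19). The metallothionein genes Mt3 (-1.15) and Mt2 (-0.96), which encode small metal-binding proteins, fell as well. Ptgr1 (-1.11), Csta2 (-1.09), Cystm1 (-1.01), H2bc14 (-0.93), Marcksl1 (-0.92) and Gcat (lower by a factor of 2.05) complete the 12. Csta2 and the histone gene H2bc14 belong to families with near-identical copies, so their values are uncertain. Exons of Mt2 share 73.5% of their bases with the opposite-strand gene Gm45774, and those of Gcat share 12.1% with Galr3.

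The genes of fatty acid handling did not move as one block. Of 24 fatty acid oxidation genes tested, 4 rose, 0 fell and 20 did not pass, and the same 4 risen and 0 fallen were counted when adjusted over the list alone. Beside Cpt1a, the risen members were Slc25a20, the carnitine-acylcarnitine carrier of the inner mitochondrial membrane (0.66), Acadvl (0.35) and Eci1 (0.27). The beta-oxidation genes further along the pathway, such as Hadha (-0.10), Acadl (-0.02) and Acadm (-0.25), did not pass. The list itself did not pass with camera, a test of a gene list against the other genes (adjusted p = 0.138), except without BSA replicate 2 (adjusted p = 0.0273). Exons of Acadvl share 42.9% of their bases with Dvl2 on the other strand, and Eci1 did not pass without BSA replicate 1 or 3 or without any 1 of the PA replicates (adjusted p up to 0.137), nor in 5 alternative fits with all 6 libraries.

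Of 14 PPAR-responsive genes tested, 6 rose and 1 fell, with the same 6 and then 2 fallen when adjusted over the list alone. The lipid droplet coat gene Plin2 went from 32.2 ± 4.16 to 54.9 ± 3.54 RPKM (0.76 ± 0.09, adjusted p = 0.000133), the droplet protein gene Hilpda rose by 0.66 and Acot2 by 0.70, while the fatty acid binding protein gene Fabp5 fell (-0.24), and 0 fell without BSA replicate 2 or PA replicate 1 or 3. Acot2 has near-identical relatives and its value is uncertain. The list passed as higher with the preset correlation (camera adjusted p = 0.00854) and did not pass at adjusted p = 0.220 with an estimated correlation. Of 22 genes of fatty acid uptake, activation and lipid storage, 3 rose (Dgat2, Plin2 and Hilpda) and 5 fell, and adjusted over the list alone 4 rose and 5 fell. Dgat2 went from 20.1 ± 3.14 to 61.9 ± 4.66 RPKM (n = 3), while Dgat1, the other enzyme of the last step of triglyceride synthesis, fell (-0.52), as did the acyl-CoA synthetase genes Acsl3 (-0.54), Acsl4 (-0.50) and Acsl5 (-0.45). The list did not pass (adjusted p = 0.301), and its median (-0.09) and mean (0.01) differ in sign. In mm10, Dgat2 (Entrez 67800) lies on chromosome 7 (positions 99153663 to 99182713), Cpt1a (12894) on chromosome 19 (3322326 to 3385735) and Plin2 (11520) on chromosome 4 (86626910 to 86670217). Values of Cd36 and Pdk4 were not analysed here.

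Cholesterol synthesis and uptake genes fell together. Of 23 tested, 18 fell and 0 rose, and 21 fell when adjusted over the list alone, with a median log2 fold change of -0.55. Hmgcs1 fell (-0.90 ± 0.07 SE, adjusted p = 2.47e-05), and Idi1 (-0.82), Fdps (-0.64) and the squalene epoxidase gene Sqle (-0.57) fell with it. The genes of the sterol sensor Insig1 (-0.49) and the transcription factor Srebf2 (-0.28), which drives this pathway, also fell, and Ebp, with a log2 fold change of 0.11, did not pass. The list passed at a camera adjusted p of 2.10e-16 and at adjusted p = 0.0157 with an estimated correlation, the only one of the 22 lists to do so. Hmgcs1 (Entrez 208715) lies on chromosome 13 (119690351 to 119708260). Exons of Fdps share 26.7% of their bases with a predicted gene on the same strand, and those of Hmgcs1 share 12.1% with one on the opposite strand.

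In the list of fatty acid synthesis and desaturation, 10 of 18 genes tested fell and 1 rose, and adjusted over the list alone 12 fell and 1 rose. The desaturase genes moved furthest: Fads2 (-0.92), Scd1 (-0.84), Fads1 (-0.76) and Scd2 (-0.60) fell, as did the fatty acid synthase gene Fasn (-0.53) and Srebf1 (-0.33). Scd1 was expressed at a low level, 2.64 ± 0.364 RPKM in BSA and 1.03 ± 0.174 in PA. The elongation gene Hacd3 rose by 0.52. With camera the list passed at an adjusted p of 6.38e-06 and did not at adjusted p = 0.135 with an estimated correlation. Of 8 LXR targets, genes induced by the oxysterol receptor, 2 rose and 3 fell, and 3 rose and 3 fell when adjusted over the list alone. The cholesterol exporter gene Abca1 rose by 0.58, from a mean of 0.962 RPKM in BSA to 1.96 in PA, and by 0.53 to 1.02 across the fits. Smpdl3a rose by 0.32, and Scd1, Srebf1 and Lpcat3 (-0.32) fell. The LXR list did not pass (adjusted p = 0.673).

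Genes of the cell cycle and DNA replication fell almost without exception. Of 31 tested, 30 fell and 0 rose, and the count adjusted over the list alone was also 30, with a median log2 fold change of -0.57. Ccnb2 went from 171 ± 6.22 to 102 ± 3.49 RPKM (-0.74 ± 0.06, adjusted p = 1.59e-05) and the mitotic kinase gene Aurka from 40.1 ± 2.09 to 22.6 ± 1.00 RPKM (-0.80 ± 0.07, adjusted p = 2.67e-05). Ccna2 (-0.77), the ribonucleotide reductase gene Rrm1 (-0.62) and the replication helicase gene Mcm5 (-0.53) fell too. The proliferation marker Mki67 fell (-0.45, adjusted p = 0.0119), with an adjusted p of 0.0505 without PA replicate 3. E2f1 (-0.17) did not pass. The list had the smallest camera adjusted p of all lists (1.50e-28), and the call was not kept at adjusted p = 0.113 with an estimated correlation.

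Glycolysis and hypoxia genes were lower by smaller amounts: 11 of 22 tested fell, 0 rose, and 12 fell when adjusted over the list alone. Without PA replicate 3, 7 fell. Examples are the lactate exporter gene Slc16a3 (-0.48), Pgk1 (-0.40), Pkm (-0.33) and Bnip3 (-0.32), while Gapdh (-0.15) and Aldoa (-0.01) did not pass. As a list they passed at a camera adjusted p of 1.36e-07 and did not at adjusted p = 0.0834 with an estimated correlation. Of the 42 genes of oxidative phosphorylation, 1 rose (Ndufa1, 0.33) and 1 fell (Uqcrfs1, -0.25), with the same counts adjusted over the list alone, and a list adjusted p of 0.482. Atp5b (-0.17) and Sdhb (-0.16) did not pass. Without BSA replicate 3, 6 of the 42 rose, and without PA replicate 2 Ndufa1 did not pass (adjusted p = 0.0594). The median of this list is above 0 and its mean below 0, both by less than 0.01, and the median was 0.07 without BSA replicate 3 and -0.03 without BSA replicate 1.

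Genes that mark Tregs were mostly higher in PA. Of 20 tested in the Treg identity list, 12 rose and 2 fell, and 13 rose and 2 fell when adjusted over the list alone. The integrin gene Itgae, which encodes CD103, went from 154 to 252 RPKM (0.70 ± 0.06 SE, adjusted p = 2.96e-05). Lrrc32, which holds latent TGF-beta on the cell surface, rose by 0.59, the adenosine-producing enzyme gene Nt5e by 0.45 and the cytokine subunit gene Ebi3 by 0.43. Foxp3 (Entrez 20371), on chromosome X (7579676 to 7595243), rose by 0.36 ± 0.07 (adjusted p = 0.00579), and 31.5% of its exon bases are shared with Flicr, Ccdc22 and Gm36995. Ikzf2 rose by 0.26, a call that was lost without BSA replicate 2 or 3 or PA replicate 1 or 2 (adjusted p up to 0.113). Entpd1 and Lag3 fell (both -0.60), and the log2 fold changes of Il2ra (-0.04) and Ctla4 (-0.12) did not pass. The list passed at a camera adjusted p of 0.000537 and did not at adjusted p = 0.135 with an estimated correlation.

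In the list of tissue Treg and PPARg-associated genes, 9 of 26 rose, 2 fell and 15 did not pass, and 12 rose and 5 fell when adjusted over the list alone. Il1rl1, which encodes the IL-33 receptor ST2, went from 52.5 ± 9.05 to 93.3 ± 8.45 RPKM (0.83 ± 0.10, adjusted p = 0.000240), and the type 2 transcription factor gene Gata3 from 51.6 ± 6.36 to 83.7 ± 2.52 RPKM (0.70 ± 0.08, adjusted p = 0.000162). Lgals3 (0.64) and Rora (0.50) rose as well. Pparg (Entrez 19016), on chromosome 6 (115360879 to 115490404), fell from 7.56 ± 2.18 to 3.78 ± 0.407 RPKM (-0.81 ± 0.15, adjusted p = 0.00318), in mice whose Pparg locus carries the reporter. Areg (-0.13), Klrg1 (-0.09) and Batf (0.17) did not pass. Il10 rose by 0.23, and did not pass without BSA replicate 1 or any 1 of the PA replicates (adjusted p up to 0.129), nor in 4 alternative fits with all 6 libraries. The list passed at a camera adjusted p of 0.0362, with 0.135 as the adjusted p with an estimated correlation, and it did not pass without BSA replicate 1 (adjusted p = 0.0628) or without PA replicate 1 (adjusted p = 0.0844). It also did not pass without the variance trend (adjusted p = 0.0948) or without the filter, and 1 gene fell in place of 2 without PA replicate 1 or 3.

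**Figure D2:**
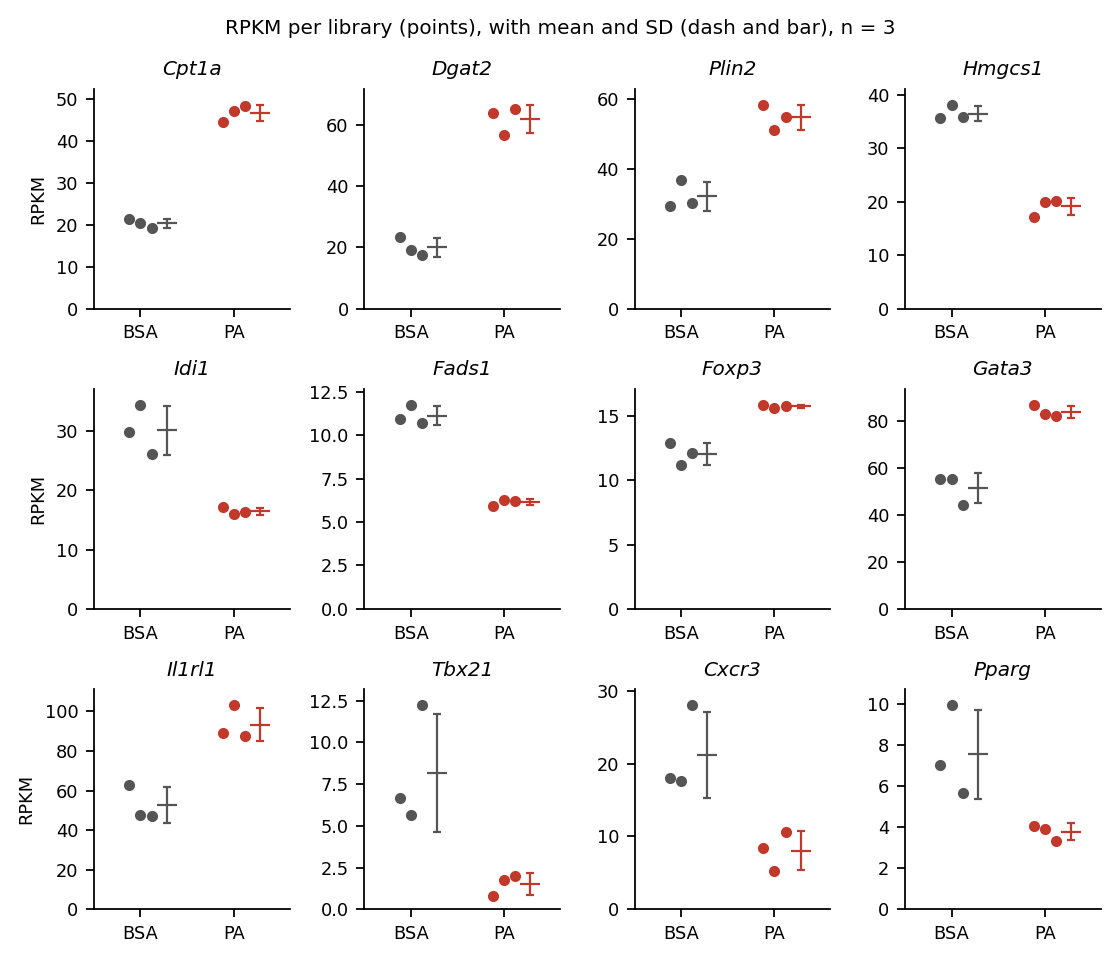
RPKM of 12 named genes in each library, with BSA in gray and PA in red, one point per library, and the mean with its SD (n = 3) beside the points. In each of the 12 panels the 3 PA values lie on one side of the 3 BSA values, as for Cpt1a (20.4 against 46.7 RPKM on average) and Tbx21 (8.17 against 1.53).

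Cytokine and homing genes moved in both directions. All 8 members of the T helper and effector cytokine list that were tested passed, over all genes and adjusted over the list alone: Ccr6, Il4, Lta (1.02), Tnf (0.63) and Maf (0.29) rose, and Tbx21, Cxcr3 and Tnfsf11 (-0.48) fell. As a list they did not pass (adjusted p = 0.138), but the 7 with enough signal for a filter at 5 RPKM did (adjusted p = 0.0279), and values of Il17a were not analysed here. Tbx21 (Entrez 57765), on chromosome 11 (97098007 to 97115331), was lower in all 3 PA libraries, at 0.784 to 2.02 RPKM, than in the BSA libraries, at 5.64 to 12.2 RPKM. In the migration and residency list, 10 of 22 rose and 3 fell, and 12 rose and 3 fell when adjusted over the list alone. Beside Ccr6, Cxcr4 and Itgae, the risen genes included Klf2 (0.59), a transcription factor of T cell trafficking, and Ccr10 (0.58), a skin-homing chemokine receptor. Cxcr3 and the egress receptor gene S1pr1 (-0.24) fell. These genes as a list passed at a camera adjusted p of 0.0111 and did not at adjusted p = 0.135 with an estimated correlation. Of 21 genes of the IL-2 and STAT5 response, 9 rose and 3 fell, and 12 rose and 4 fell when adjusted over the list alone. The feedback inhibitor genes Cish (0.52) and Socs1 (0.37), Pim2 (0.45) and Ccnd2 (0.35) rose, the perforin gene Prf1 fell (-0.70), and Bcl2 (0.22) did not pass. The list passed at a camera adjusted p of 0.0177 and did not at adjusted p = 0.135 with an estimated correlation or at adjusted p = 0.0551 without the variance trend. Without PA replicate 1 or 2, 1 gene fell in place of 3.

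Among genes of NF-kB and inflammation, 13 of 20 tested rose and 1 fell, and 15 rose and 1 fell when adjusted over the list alone, with a median log2 fold change of 0.35. Beside Cd83 and Tnf, Nfkbiz (0.81), the inhibitor gene Nfkbia (0.60) and the subunit genes Rel (0.79) and Nfkb1 (0.43) rose. The chemokine gene Ccl5 fell (-0.62), though not without BSA replicate 1 or 3 or PA replicate 1 or 3. Nfkbia went from 172 to 261 RPKM. The NF-kB list passed at a camera adjusted p of 4.24e-08 and did not at adjusted p = 0.113 with an estimated correlation. In the TCR-induced activation list, 7 of 19 rose and 2 fell, and 10 rose and 3 fell when adjusted over the list alone, but the list did not pass (adjusted p = 0.126). Leaving out BSA replicate 1, PA replicate 1, 2 or 3 left 4, 3, 4 and 2 risen, and 1 fell in place of 2 without BSA replicate 2 or PA replicate 1 or 2. Egr2 (1.04) and Egr1 (0.65) rose and the phosphatase gene Dusp4 fell (-0.68). Dusp2 rose by 0.43 and Cd44 by 0.29, and Zbtb32 fell (-0.38); the calls of Dusp2 and Cd44 were lost without PA replicate 3, that of Dusp2 also without BSA replicate 1, and that of Zbtb32 without BSA replicate 2 or PA replicate 1 or 2 (adjusted p up to 0.0927). Of 14 interferon response genes, 3 fell (Isg15, -0.66; Isg20, -0.57; Bst2, -0.45) and 0 rose, and 4 fell and 1 rose when adjusted over the list alone. The calls of Isg15 and Isg20 were lost without PA replicate 1 or 2, and that of Isg15 also without BSA replicate 1 or 3 (adjusted p up to 0.0922). The log2 fold change of Isg20 was -0.36 without BSA replicate 3. Rtp4 (-0.34) did not pass with all libraries and passed without PA replicate 3 (adjusted p = 0.0495) and after quantile normalization. The interferon list did not pass (adjusted p = 0.154), but did without BSA replicate 2 (adjusted p = 0.00618) and without PA replicate 3 (adjusted p = 0.0224). Without BSA replicate 3 its median changed sign to 0.03, with 3 genes risen and 2 fallen (adjusted p = 0.986), and without PA replicate 1 or 2 only 1 gene fell.

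Stress genes changed in part. In the unfolded protein response list, 5 of 24 rose and 1 fell, and 7 rose and 1 fell when adjusted over the list alone. Ddit3, which encodes the stress factor CHOP, rose by 0.59 ± 0.14 (SE) from a mean of 8.94 RPKM (adjusted p = 0.0118), Pdia4 and Herpud1 rose (both 0.31), and Edem1 fell (-0.39). The chaperone gene Hspa5 (0.17) did not pass, but passed without BSA replicate 3 (adjusted p = 0.0480) and in 4 of the alternative fits that keep all 6 libraries (lowest adjusted p = 0.0288). The list did not pass (adjusted p = 0.121), but did without BSA replicate 3 (adjusted p = 0.0266) and without PA replicate 3 (adjusted p = 0.0491), and with all libraries after quantile normalization (adjusted p = 0.0417). Without BSA replicate 1 or PA replicate 3, 3 genes rose. Of 22 genes of the ATF4 response, 6 rose and 5 fell, and 6 rose and 9 fell when adjusted over the list alone. Without BSA replicate 2 or PA replicate 2, 3 fell. Trib3 (0.81) and Cebpb (0.60) rose, while the serine synthesis gene Psat1 (-0.49) and Ddit4 (-0.42) fell. The ATF4 list did not pass (adjusted p = 0.673), and its median (-0.03) and mean (0.03) differ in sign. The median was -0.11 without BSA replicate 1 and 0.05 without BSA replicate 2. Of 22 NRF2 and oxidative stress genes, 6 rose and 3 fell, and 7 rose and 3 fell when adjusted over the list alone. Only 2 rose without BSA replicate 1 or 2 or PA replicate 1 or 3, and 3 without PA replicate 2. Nqo1 (0.47) and Sqstm1 (0.41) rose and the metallothionein genes Mt1 (-0.79) and Mt2 fell, with a list adjusted p of 0.438.

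Of 19 apoptosis and p53 genes, 2 rose and 1 fell, and 3 rose and 1 fell when adjusted over the list alone. Fas rose by 0.66 and Sesn1 rose by 0.34. Mcl1 (0.16) did not pass, and neither did the list (adjusted p = 0.323). Of 28 lysosome and autophagy genes, 7 rose and 2 fell, and 10 rose and 4 fell when adjusted over the list alone, with a list adjusted p of 0.173. Only 2 rose without BSA replicate 2 or PA replicate 3, 4 rose and 0 fell without PA replicate 1 or 2, and 1 fell without BSA replicate 1 or 3 or PA replicate 3. Sqstm1 and Flcn (0.38) rose, and Ctsb and Grn fell (both -0.23). The call of Ctsb was lost without PA replicate 1 or 2 and that of Grn without any 1 library other than BSA replicate 2 (adjusted p up to 0.0890).

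**Figure D3:**
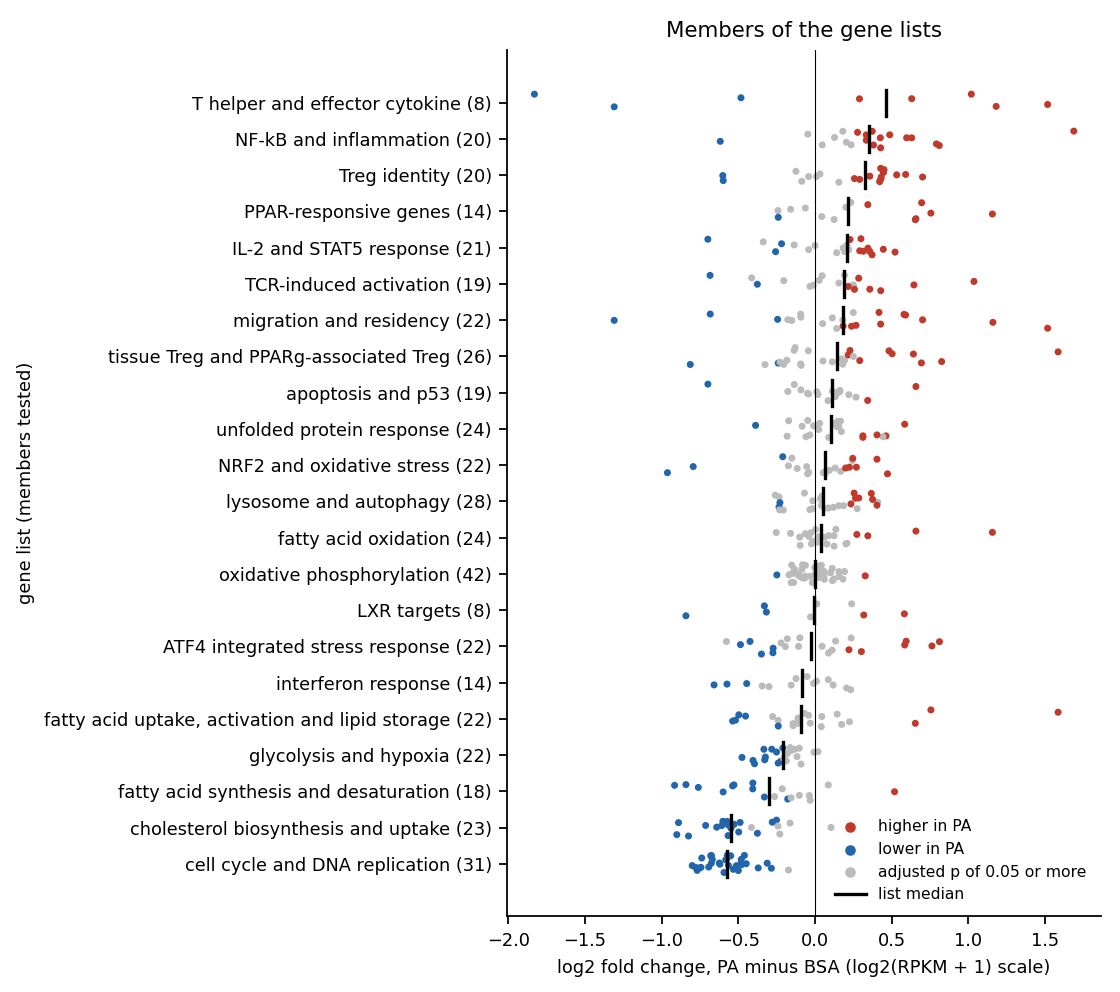
Log2 fold change (PA minus BSA, on the log2(RPKM + 1) scale) of every tested member of the 22 gene lists, one point per gene, red where higher, blue where lower and gray where the gene did not pass. Black bars mark list medians, the lowest being those of the cell cycle (-0.57) and cholesterol (-0.55) lists.

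Markers of other cells of the skin were mostly at low levels or below the filter, and 0 of the 6 lists with a tested member passed at a camera adjusted p below 0.05. Each of these 6 lists was tested on only 1 to 3 members, because most of its markers were not listed, so this count says little about other cells. With single genes tested by limma, Kit, a mast cell marker, rose from 2.68 ± 0.295 to 6.54 ± 1.23 RPKM (log2 fold change 1.02, adjusted p = 0.000235) and was the only member of its list with a value. The mast cell list, at an adjusted p of 0.115, passed without PA replicate 3, and with an unadjusted p below 0.05 it was the only one of the 6. The B cell gene Cd79a rose by 0.36 and Cd79b (0.27) did not pass, with summed values of both at 12.7 ± 1.29 and 15.9 ± 1.56 RPKM. Keratinocyte markers summed to 33.1 ± 1.17 RPKM in BSA and 31.9 ± 4.08 in PA, and of these Perp fell (-0.28). Cd74 and H2-Ab1 summed to 21.7 ± 0.716 and 19.3 ± 2.66 RPKM. Cd8b1 stood at 11.4 ± 1.07 and 11.6 ± 2.01 RPKM, the erythroid and endothelial markers at 11.3 ± 0.249 and 10.3 ± 0.567, the collagens and other fibroblast markers at 2.71 ± 0.210 and 3.05 ± 0.277, and the neutrophil gene Mmp9 at 1.16 ± 0.521 and 0.544 ± 0.0311.

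Of the 22 program lists, 6 passed as higher and 4 as lower in PA with camera at its preset correlation of 0.01, and 1 passed with an estimated correlation. Fold changes on the log2(RPKM + 1) scale understate the change of genes at low levels, and 15 of the 108 named genes share 10% or more of their exon bases with another gene, so that reads of both cannot be separated where strand was not used in counting.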

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

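Across the 18 alternative fits the number of genes higher in PA ran from 555 to 1025 and of genes lower from 622 to 1061, and 0 genes called in the main comparison changed sign. Leaving out 1 library gave 555 to 754 higher and 622 to 779 lower genes, 9 to 12 program lists and 0 to 1 marker lists; the fewest higher genes, 555, came without BSA replicate 2 and the marker list, that of mast cells with Kit alone, without PA replicate 3. Fewer samples were fitted in these, and they shared 1133 (without BSA replicate 2) to 1352 (without BSA replicate 1) of the 1785 calls of the main comparison. With an estimated correlation camera called 1 program list in place of 10. The estimate lay below the preset 0.01 for the tissue Treg (-0.024), IL-2 and STAT5 (-0.003) and migration (0.0009) lists. Their camera p still rose, for migration from 0.0040 to 0.035 before adjustment, so a higher correlation does not account for those losses. For the other lists lost the estimate was above 0.01, up to 0.37 for the cell cycle. The fry test called 14 program lists, but it does not compare a list with other genes. The median log2 fold change of all genes was 0.02 and at most 0.03 when rounded, under any scaling. Quantile normalization gave 837 higher and 925 lower genes, with 1598 calls shared with the 1785 of the main comparison, and voom on the recovered reads gave 1025 and 993 (1642 shared). A threshold of 0.1 was also tried. Of 97 called named genes, 85 passed in every fit in which they were tested (Abca1 and Scd1 were not, with the filter at 5 RPKM); each of the 12 others was lost when some library was left out, and with all 6 libraries Eci1 was lost in 5 fits, Il10 in 4, Grn in 2 and Ctsb, Dusp2, Ikzf2, Isg15 and Zbtb32 in 1. Another 6 (Atp5b, Batf, Hspa5, Mcl1, Rtp4 and Sdhb) passed only in an alternative. Named genes other than the anchors were chosen for large changes or small p-values, so the share kept among them does not stand for all called genes. With the replicate number as a block 786 genes were higher and 856 lower, 10 program lists and 0 marker lists passed. Same-numbered libraries deviated from their group means with correlations of -0.08, -0.03 and 0.10, and not every library correlated best with its own number, so a pairing is not shown; both replicate 3 libraries lay together on the second principal component. The tests planned for a count table (edgeR and DESeq2) were not run, because the unit is RPKM. Of simulated changes, with genes drawn independently, 66% of those of 1.5-fold and 28.6% of the smallest were called.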

Other observations

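Gene groups in this part were put together after the values had been seen, so their tests describe these data and are not independent evidence; the weighed patterns were picked after the fold changes were seen, the correction for GC content and gene length was added after the data were seen, and what each test should show was written before its outcome was seen only for the cell cycle genes and the splits. Most listed genes of the type 1 and type 2 groups of T helper genes went opposite ways. Ifng, Il12rb2, Fasl and Ly6c2 of the type 1 group and Il5, Il13 and Ptgdr2 of the type 2 group have no listed values. Of 11 type 1 genes tested, 8 fell and 0 rose, including Prf1 (-0.70), Ly6c1 (-0.65) and Il12rb1 (-0.36) beside Tbx21, Cxcr3, Nkg7 and Ccl5, while Stat4 (0.29) and Il18r1 (0.20) did not pass. When adjusted over the group alone, 8 fell and 1 rose (Stat4). Of 11 type 2 genes, 8 rose and 0 fell, among them Il4 (1.18), the eotaxin receptor gene Ccr3 (0.85), Il1rl1 (0.83), the IL-25 receptor gene Il17rb (0.63) and Stat6 (0.44), while Ccr8 (-0.09) and Il4ra (0.11) did not pass. Kit, a marker of mast cells, which also express Il4 and Il1rl1, rose with them (1.02). The mast cell and basophil markers Cpa3, Cma1, Mcpt4, Tpsb2, Fcer1a, Ms4a2, Hdc, Mcpt8 and Gata2 are not among the listed genes. All listed genes reached 3 RPM in every library of at least 1 group, so no marker of that list other than Kit is seen at this level. Over the 13 groups of this part, the camera adjusted p was 0.000338 for type 1 and 5.48e-06 for type 2. With an estimated correlation the camera adjusted p was 0.164 and 0.113. Of 25 TNF family ligands and receptors, 12 rose and 3 fell: beside Tnfrsf25, Tnfsf8 (1.21), Cd40lg (1.10), Lta (1.02) and Ltb (0.97) rose, and Tnfsf11 (-0.48) and Tnfrsf1a (-0.39) fell (camera adjusted p = 1.20e-05, and adjusted p = 0.113 with an estimated correlation). Of 22 interleukin receptor genes, 10 rose and 1 fell, with Il7r going from 43.4 ± 5.57 to 74.4 ± 5.39 RPKM (camera adjusted p = 4.82e-05, and adjusted p = 0.113 with an estimated correlation).

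Clock genes were higher in PA: 6 of 11 tested rose and 0 fell, led by the nuclear receptor genes Nr1d1, from 0.789 to 2.74 RPKM (1.04), and Nr1d2 (0.68), with Dbp (0.52) and Bhlhe40 (0.41). Arntl (0.18) and Cry1 (0.07) did not pass (camera adjusted p of the group 2.14e-05, and adjusted p = 0.113 with an estimated correlation). All 3 metallothionein genes listed fell, Mt1 from 132 ± 7.68 to 76.7 ± 14.7 RPKM (camera adjusted p = 0.000103, and adjusted p = 0.113 with an estimated correlation). Of 14 class I MHC heavy chain genes, 7 rose and 0 fell, such as H2-Q6 (0.85) and H2-K1 (0.41), with H2-D1 (0.26) not passing; these genes are near-identical in part, so reads of one can be counted for another (camera adjusted p = 0.000111, and adjusted p = 0.290 with an estimated correlation). Of 11 tubulin genes 7 fell and 0 rose (camera adjusted p = 2.12e-06, and adjusted p = 0.113 with an estimated correlation), and of 33 replication-dependent histone genes 11 fell and 1 rose (2.12e-06, and 0.290 with an estimated correlation). In each of these 11 the highest BSA value was that of BSA replicate 3, as for H2ac8 with 76.8, 77.8 and 135 RPKM in BSA replicates 1 to 3. Of 10 Kruppel-like factor genes 6 rose and 0 fell (camera adjusted p = 0.000259, and adjusted p = 0.164 with an estimated correlation). Of 37 proteasome genes 3 fell and 0 rose, and 0 fell when adjusted over the group alone (camera adjusted p = 0.0191, and adjusted p = 0.485 with an estimated correlation). The 76 cytosolic ribosomal protein genes showed 0 calls in limma. Thy1 rose from 21.1 ± 1.37 to 27.5 ± 0.923 RPKM, by a factor of 1.31. Its Thy1.1 form is also part of the Foxp3 reporter, so reads of the gene and the reporter cannot be separated here. Thy1 was chosen after its values were seen.

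Cell cycle genes were lower in PA, with a median log2 fold change of -0.57 over 31 genes. A difference in scaling between libraries would bring this median to near 0 once the libraries are given one distribution, but after quantile normalization it was -0.55. The median of all genes tested was already 0.02 in the main fit. A scaling difference common to all genes was thus small beforehand, and the normalization could move the cell cycle median only little. A trend with GC content and gene length was also argued against, since the median was -0.57 after that trend was removed. A lower share of dividing cells in PA and a lower level of these transcripts per cell both stay open and were not tested.

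Of 23 cholesterol genes tested 18 fell in PA, and the median log2 fold change of the 23 was -0.55. The median was -0.53 after quantile normalization and -0.56 after removing the trend with GC content and gene length. That trend thus does not account for the pattern. The median of all genes tested was already 0.02, so a scaling difference common to all genes was small beforehand. Quantile normalization could move the cholesterol median only little. An effect of the added fatty acid on the sterol-regulated transcription program may be the source, but this was not tested, and no protein or lipid measurement was analysed here.

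Of 11 type 1 genes tested 8 fell in PA and the other 3 had positive values that did not pass; the median of the 11 was -0.65 and stayed near that after quantile normalization (-0.66) and after removal of the trend with GC content and gene length (-0.65). Here too the normalization could move the median only little, since the median of all genes tested was already 0.02. Another candidate explanation is a few CD8 T cells in the BSA libraries, although live Tregs were sorted again after culture. Of 17 transcripts chosen as abundant in such cells, Cd8a, Gzma, Gzmk, Klrd1, Klrk1, Klrc1, Klrc2 and Xcl1 have no listed values. Their fold changes could not be compared. Since all listed genes reached 3 RPM in every library of at least 1 group, these transcripts are not seen at that level in all 3 BSA libraries. The 9 tested had a median log2 fold change of -0.14 and went both ways, but 3 of the 4 that fell (Nkg7, Prf1 and Ccl5) belong to the type 1 group itself. Of the 6 outside it Cst7 fell (-0.32), Ctsw rose (0.53) and Gzmb (-0.14), Itga2 (-0.08), Cd7 (-0.01) and Cd8b1 (0.02) did not pass, and since they go both ways the explanation is left open. A shift among Treg subsets and a change within each cell stay open and were not tested.

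The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. Every split other than the real grouping puts PA and BSA libraries on both sides, so a difference between PA and BSA adds to the spread within each side. Counts in those splits therefore do not show what would be called without an effect. The real grouping gave 870 higher and 915 lower genes, and the highest count of any other split was 0 (1 of 10 splits with a count as large, for each). For program lists with the preset correlation the real grouping gave 10 and the highest other 9 (1 of 10 splits). For marker lists the real grouping gave 0 and the highest other 1, so that 10 of 10 splits had a count as large.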
